A study of Mus musculus with 2 samples.

How the data were processed

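Nuclei were taken from the visual cortex of PV-Cre mice on the C57BL/6J background that carried a Cre-dependent optoTrkB construct, a light-activated form of the BDNF receptor TrkB. PV-Cre restricts recombination to parvalbumin interneurons. Per the labels' protocols, tissue was broken up in a Dounce homogenizer and passed through a 35 µm strainer, and libraries were made with the 10x Genomics Chromium 3' v3 kit, which primes on polyadenylated RNA and tags each captured molecule with a unique molecular identifier (UMI). The labels name 2 libraries, 1 light-stimulated and 1 non-light-stimulated. They are called with and without light here, which refers to this stimulation and not to the lighting the animals were kept in. They do not say how many animals entered each library.

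The values used are the authors' deposited raw UMI counts per gene and barcode of the library without light, with every barcode kept. Cell Ranger 3.0.1 and the mm10 build are named in the submitters' processing notes. Whether reads in introns were counted is not given in the sources used here. The reference holds 31053 mouse genes and 1 transgene feature. Counts of the library with light were not analysed here, so no value sets light against no light. The barcode and feature lists of both libraries were identical and carry no measurement.

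Barcodes with at least 1000 UMIs, at least 500 detected genes and at most 5% mitochondrial UMIs were taken as nuclei. Scrublet, as implemented in scanpy 1.11.5, was run with an expected doublet rate of 0.06. It set a threshold of 0.540 and marked 8 of 3717 barcodes (0.215%), which is few for this number of nuclei, so doublets of unlike cells were also looked for by cluster. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes were reduced to 30 principal components, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 (igraph 0.11.9). Genes of the 10 fixed lists, mitochondrial genes and the transgene feature were left out of the clustering, so that list values within a class are not set by it. GABAergic-like clusters were clustered again in the same way.

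Cell type markers, gene lists, filters, comparisons and the rule for named genes were fixed before the data were examined. The scoring rule that turns markers into names was set after clusters had been seen. For each cluster, each marker's CPM (UMIs at the usual scaling to the total) were divided by the marker's highest CPM over clusters (or by 50 CPM if that was higher) and averaged per type. The best type named the cluster if its score reached 0.35, if at least 3 of its markers had a UMI in at least 5% of the nuclei, and if the 10 leading genes held no more markers of another type than of its own. Clusters with a median UMI count more than 3 times lower than the library's and no marker of their own among the leading genes stayed unnamed. A sub-cluster of 33 nuclei (6.76% of 488 GABAergic nuclei) with at least 2 glutamatergic markers among its leading genes, a median of 16286 UMIs and a median doublet score of 0.357 was left out of every class, also by a rule set after it had been seen. Of the marker sets, those of glutamatergic, GABAergic and astrocyte cells named clusters in the first round, and those of PV, SST, VIP and LAMP5 or SNCG interneurons in the second. The sets for oligodendrocytes and their precursors, microglia, endothelial, mural and leptomeningeal cells, and thalamic, striatal and hippocampal neurons named no cluster.

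UMIs were summed per class and expressed as CPM of the class total. PV-like nuclei were compared with the other GABAergic-like nuclei and with glutamatergic-like nuclei. Log2 ratios used a pseudocount of 0.5 UMI. Genes with at least 50 UMIs over both classes were measured. With 1 library, nuclei are not replicates, so no p-value or standard error is given. Sums carry exact 95% Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals. All of them cover counting error only, not differences between animals or preparations. A count of 0 is given an upper limit of 3 counts. List medians carry intervals from 1000 Poisson redraws and a percentile among 10000 random lists matched on mean expression in 20 bins. Of 396 listed genes, 393 were in the reference.

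Named genes are, in each list and comparison, the 2 with the highest ratio if at least 2-fold and the 1 with the lowest if at most 0.5-fold. Ntrk2, Bdnf, Kcnc1, Kcnc2 and Acan are always given. Of the genes this rule picks, a few are not reported here. Any other gene named was chosen after its values were seen. Gene positions are from the GENCODE vM21 annotation of GRCm38, the assembly behind mm10, matched on gene identifier.

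Shares of nuclei with a UMI were compared after thinning each nucleus to 4000 UMIs, leaving out shallower nuclei. For free RNA, the alternative fixed beforehand subtracted the profile of barcodes with 1 to 100 UMIs, and an added one that of barcodes with at least 250 and under 500 UMIs, a plateau of 30715 barcodes with a median of 274 UMIs. The profiles differed in composition. Ly6c1 stood at 477 CPM in barcodes of 1 to 100 UMIs and 2.18 CPM in the plateau, Flt1 at 406 and 1.26 CPM, C1qa at 187 and 6.75 CPM, and Xist at 74.8 and 0.229 CPM. Xist had 21 UMIs in all retained nuclei, so the first profile is not shown to be free RNA of these nuclei. Values with it subtracted are given as a processing alternative. Scaled on the glutamatergic markers in PV-like nuclei, the profiles came to 17.0% and 6.99% of their UMIs. At 274 UMIs per droplet the share of free RNA would be 2.77%. The amounts expected from free RNA that are given for single genes use this level, the lowest of the 3.

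The ratio and clustering steps were tested on simulated data. In the simulated comparison of PV-like with other GABAergic-like nuclei over 8942 genes, 95.5% of true ratios lay inside their intervals, 100% of genes changed 4-fold passed 2-fold, 0.240% of unchanged genes passed 2-fold in either direction, and 1 of 10 lists without an effect fell in the outer 5% of matched lists. These class sums were drawn from the Poisson model that the intervals assume. Their coverage therefore checks the code and does not cover spread between nuclei. Among 3353 simulated nuclei, 100% of PV-like nuclei were recovered and 100% of nuclei named PV-like were correct, in data simpler than real nuclei. Alternatives covered the filters on nuclei, doublet removal, clustering resolution, list genes in the clustering, free RNA, class profiles, gene filters, class totals and a split of the counts between clustering and measurement. A further 5 were added after the data had been seen. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.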

Results

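The study profiled single nuclei of mouse visual cortex in which parvalbumin (PV) interneurons, fast-spiking inhibitory neurons, had been targeted with optoTrkB. It set a library after light stimulation beside a library without it. The labels give a blue LED of 370 nm, which is not a blue wavelength. There was 1 library per group. The library without light held 59135085 UMIs in 1040281 barcodes, and 0.285% of its UMIs came from mitochondrial genes. After filtering, 3709 nuclei were retained, with a median of 10251 UMIs (range 1004 to 42651) and 3647 detected genes. They held 68.3% of the library's UMIs. Values below describe this library alone, without a replicate check, and the light effect itself was not analysed here.

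**Figure D1:**
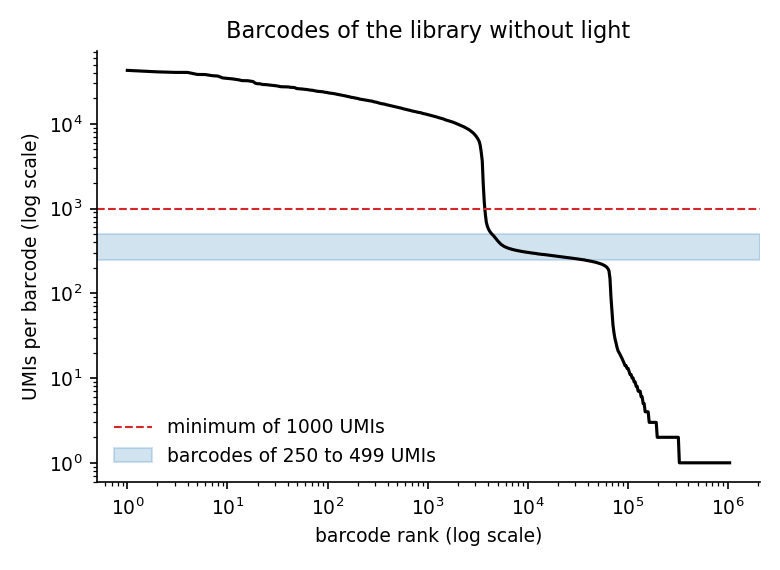
UMIs per barcode against barcode rank, both on log scales, for the library without light; the dashed line marks the minimum of 1000 UMIs and the band barcodes of at least 250 and under 500 UMIs. The curve drops steeply across the minimum and then runs flat through 30715 barcodes with a median of 274 UMIs.

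The nuclei were mostly cortical neurons. Glutamatergic-like nuclei made up 2950 of the 3709 (79.5%, exact 95% interval 78.2 to 80.8%). The 455 GABAergic-like nuclei made up 13.4% of the 3405 neuronal nuclei (12.2 to 14.6%), and 16 nuclei were astrocyte-like. Another 255 nuclei stayed unnamed. Among GABAergic-like nuclei, 144 were PV-like, a share of 31.6% (27.4 to 36.1%). SST-like nuclei made up 23.3%, VIP-like nuclei 17.6%, LAMP5/SNCG-like nuclei 16.0% and nuclei of no named class 11.4%. The share of GABAergic-like nuclei among neuronal nuclei was 15.6% with at most 1% mitochondrial UMIs and 15.4% at resolution 2.0. It was lowest, at 12.7%, when leading genes of another type were ignored in naming. That setting adds an unnamed cluster of 182 nuclei to the glutamatergic-like class.

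Among class markers, Pvalb stood at 159.6 CPM in PV-like nuclei, 5.70 CPM in other GABAergic-like nuclei and 1.89 CPM in glutamatergic-like nuclei. After thinning to 4000 UMIs, 40.6% of 133 PV-like nuclei had a Pvalb UMI (32.2 to 49.5%), against 1.72% of 291 other GABAergic-like nuclei and 0.673% of 2825 glutamatergic-like nuclei. Without thinning these shares were 68.8%, 3.86% and 1.83%. Thinning left out 11, 20 and 125 shallower nuclei, and median depths were 9741.5, 8838 and 10332.5 UMIs. Other markers of the fixed sets separated to different degrees. Tac1 stood at 42.2 CPM in PV-like and 0.356 CPM in other GABAergic-like nuclei, Penk at 117.9 CPM in VIP-like and Pdyn at 63.6 CPM in SST-like nuclei, both with 0 UMIs in PV-like nuclei. By contrast, the PV marker Pthlh stood at 8.43 CPM in PV-like and 26.6 CPM in VIP-like nuclei, Ank1 at 388 CPM in PV-like and 265 CPM in SST-like nuclei, and the LAMP5/SNCG marker Reln at 1435 CPM in its own class and 849.8 CPM in SST-like nuclei. PV-like nuclei held 1422676 UMIs in all.

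The targeting construct left almost no trace in the counts. Its feature, named for tdTomato, an IRES and oPHR, had 1 UMI in the whole library, in a barcode with 1 UMI. None of the 144 PV-like nuclei had a UMI of it, which allows up to 2.08% of nuclei with a UMI and a level of up to 2.11 CPM. There was also none in 311 other GABAergic-like nuclei (up to 0.965%) or in 2950 glutamatergic-like nuclei (up to 0.102%). Nuclei that carried the construct could therefore not be picked out, and PV-like nuclei are described as a class.

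The comparison of PV-like with other GABAergic-like nuclei asks how the class that PV-Cre targets differs from the remaining inhibitory neurons without light stimulation. PV-like nuclei had higher levels of energy metabolism genes, with a median ratio of 1.42, and lower levels of glutamate receptor genes, with a median ratio of 0.722. The TrkB list as a whole lay near equality. Of 305 measured list genes, 35 were at least 2-fold higher and 52 at most 0.5-fold, against 380 and 598 of all 8980 measured genes. The median log2 ratio of all measured genes was 0.03.

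TrkB signalling genes had a median log2 ratio of -0.03 (-0.10 to 0.12, percentile 19.2 of matched lists), with 2 of 34 at least 2-fold higher and 3 at most 0.5-fold. Ntrk2, which encodes TrkB (ENSMUSG00000055254, chromosome 13, 58806569 to 59133970), stood at 892 CPM in PV-like nuclei (844 to 942, 1269 UMIs) and 841 CPM in the others (808 to 876). The ratio was 1.06 (0.990 to 1.14), and its interval includes equality. Bdnf, the TrkB ligand (ENSMUSG00000048482, chromosome 2, 109674700 to 109727007), gave 13 UMIs or 9.14 CPM (4.87 to 15.6) against 7.47 CPM (4.63 to 11.4). The ratio of 1.22 (0.562 to 2.56) shows no difference detectable at this depth, and 78.1% of its level in PV-like nuclei was the amount expected from free RNA at 274 UMIs per droplet. At the share of 6.99% scaled on glutamatergic markers, expected amounts are 2.52 times higher. Among genes the rule picked, they then exceed the level seen in PV-like nuclei for Bdnf, Nrp1, Nptx2, Cacna2d1 and Ldha. Alternatives for free RNA subtracted the profile of barcodes of 1 to 100 UMIs (low-count profile) or of the plateau of 274 UMIs (plateau profile). Whether the low-count profile is free RNA of these nuclei was not tested. Neither profile left a Bdnf UMI in either class. The ratio of 1.98 under both is set by the pseudocount and the class totals, so it says nothing about Bdnf. Ntrk3, the receptor TrkC, was 3.08-fold higher (2.78 to 3.41) and the ribosomal S6 kinase gene Rps6ka2 2.24-fold higher (1.85 to 2.71). Sorcs2, a sortilin-family receptor, stood at 0.272-fold (0.200 to 0.363).

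Voltage-gated potassium channel genes spread widely in either direction. Of 35, 6 were at least 2-fold higher and 9 at most 0.5-fold. Kcnc1 (ENSMUSG00000058975, chromosome 7, 46396497 to 46438704) and Kcnc2 (ENSMUSG00000035681, chromosome 10, 112271121 to 112467024) encode the fast delayed-rectifier channels that let these neurons fire at high rates. Kcnc1 stood at 722 CPM (678 to 767) against 302 CPM (282 to 323), a ratio of 2.39 (2.18 to 2.62), and Kcnc2 at 2309 CPM (2231 to 2389) against 1097 CPM (1059 to 1137), a ratio of 2.10 (2.003 to 2.21). After thinning, 92.5% of PV-like nuclei had a Kcnc1 UMI against 66.3% of other GABAergic-like and 23.5% of glutamatergic-like nuclei (97.9%, 86.5% and 46.3% without thinning). The auxiliary subunit genes Kcnip2 and Kcnab3 were 4.90-fold (3.71 to 6.52) and 3.61-fold higher (2.55 to 5.16). The list's median of -0.09 (-0.24 to 0.23, percentile 6.42) has no clear direction, and it was 0.26 when the other class was limited to named interneuron classes.

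Genes of the list of perineuronal net and plasticity brakes (net list) were also split. The net is the proteoglycan mesh that surrounds PV interneurons. The list also holds plasticity brakes such as Lynx1 and Rtn4r, so its median is not that of net genes alone. Acan, which encodes aggrecan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099), gave 31 UMIs or 21.8 CPM (14.8 to 30.9) in PV-like nuclei and 3 UMIs or 1.07 CPM (0.220 to 3.12) in the others, a ratio of 20.4 (6.37 to 104). The metalloprotease gene Adamts15 was 23.7-fold higher (8.68 to 90.5) and Bcan, which encodes brevican, 6.85-fold higher (4.65 to 10.4). Ptprz1, a receptor phosphatase gene, stood at 0.0883-fold (0.0526 to 0.140) and was among the leading genes of a VIP-like sub-cluster of 46 nuclei. The ratio of Acan was 41.1 with at least 500 UMIs per nucleus, 41.8 with list genes in the clustering and 83.7 in the count split. These ratios rest on fewer UMIs in the other class than the 3 above, and the last is set by the pseudocount. They are no sign of a larger difference. The split took Adamts15 to 13.1, equal weights for the SST-like, VIP-like and LAMP5/SNCG-like classes took Bcan to 11.1, and Ptprz1 lay between 0.0391 with the profile of barcodes of 1 to 100 UMIs subtracted and 0.175 with at least 2000 UMIs per nucleus. In all, 5 of 22 genes of this mixed list were at least 2-fold higher and 6 at most 0.5-fold. Its median log2 ratio was -0.26 (-0.36 to -0.04, percentile 0.600).

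Glutamate receptor genes were lower as a group, with a median log2 ratio of -0.47 (-0.56 to -0.41), below all matched lists (percentile 0.0). None of 30 was at least 2-fold higher and 12 were at most 0.5-fold. Grin3a, an NMDA receptor subunit gene, stood at 12.7 CPM against 549 CPM, a ratio of 0.0230 (0.0136 to 0.0365). It was at 807 CPM in SST-like nuclei, and the ratio was 0.0358 with equal class weights and 0.0150 with the low-count profile subtracted. GABA receptor and inhibitory postsynapse genes had a median of 0.14 (0.04 to 0.21, percentile 81.7), with 3 of 24 at least 2-fold higher and 2 at most 0.5-fold. Gabrd, the delta subunit of extrasynaptic receptors, was 3.59-fold higher (2.87 to 4.52). Gabra2 stood at 0.208-fold (0.143 to 0.295), at 0.0951-fold with the low-count profile subtracted and at 0.136-fold with the plateau profile.

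Presynaptic and calcium or sodium channel genes had a median log2 ratio of -0.13 (-0.24 to -0.04, percentile 1.02), with 4 of 43 at least 2-fold higher and 10 at most 0.5-fold. Syt2, a calcium sensor of fast transmitter release, was 23.6-fold higher (15.9 to 36.3), with 322 UMIs against 27. Cacna2d2, a calcium channel subunit gene, was 2.83-fold higher (2.47 to 3.26), and 4.96-fold higher with equal class weights. Unc13c, a vesicle priming gene, had 0 UMIs in PV-like nuclei and 776 in the others, so it was at least 131-fold lower against a floor of 3 UMIs over the class. With Unc13c at that bound, and without the pseudocount, the list's median was also -0.13. The 776 UMIs came mainly from SST-like nuclei, where Unc13c stood at 566 CPM.

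Synaptic adhesion genes had a median of 0.15 (0.05 to 0.30, percentile 91.6), with 8 of 43 at least 2-fold higher and 4 at most 0.5-fold. The neurexophilin gene Nxph2 was 10.4-fold higher (4.81 to 25.6) and the guidance cue gene Slit2 8.20-fold higher (7.03 to 9.60). Elfn1, a postsynaptic adhesion gene, stood at 0.0165-fold (0.00448 to 0.0426) and was at 268 CPM in SST-like nuclei. Slit2 was 13.1-fold higher with equal class weights and Nxph2 17.0-fold higher with at least 2000 UMIs per nucleus, while Elfn1 lay between 0.00633-fold without the top 6% of doublet scores and 0.0429-fold in the count split. Of 18 neuromodulator receptor genes, 2 were at least 2-fold higher and 6 at most 0.5-fold, with a median of -0.14 (-0.25 to 0.17, percentile 5.51) that was -0.60 when every gene with a UMI was included. The substance P receptor gene Tacr1 was 5.27-fold higher (2.85 to 10.3). Adrb1, the beta-1 adrenergic receptor gene, was 2.32-fold higher (1.54 to 3.51), though at a log2 ratio of 0.90 with SST-like, VIP-like and LAMP5/SNCG-like profiles weighted equally. Oprm1, the mu opioid receptor gene, stood at 0.112-fold (0.0529 to 0.211) and at 0.190-fold with no doublets removed. It was at 0.00846-fold and 0.0697-fold with the low-count and plateau profiles subtracted. The value of 0.00846 is set by the pseudocount, since no UMI was left in PV-like nuclei.

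Mitochondrial energy metabolism genes were the list that lay highest, with a median log2 ratio of 0.50 (0.37 to 0.59) above all matched lists (percentile 100). Of 35, 3 were at least 2-fold higher and none was at most 0.5-fold. The orphan nuclear receptor gene Esrrg (ENSMUSG00000026610, chromosome 1, 187608791 to 188214885) stood at 970 CPM against 159 CPM, a ratio of 6.08 (5.46 to 6.78), and Ppargc1a, the coactivator of mitochondrial biogenesis, was 2.88-fold higher (2.45 to 3.38). UMIs of mitochondrially encoded genes were also 1.65-fold higher (1.55 to 1.76). Immediate early genes, which neuronal activity induces, had a median of -0.10 (-0.21 to 0.22, percentile 19.8), with 2 of 21 at least 2-fold higher and none at most 0.5-fold. Jun was 2.30-fold higher (1.70 to 3.11), but at a log2 ratio of 0.82 without the top 6% of doublet scores. Dusp1 was 2.01-fold higher (1.34 to 3.02), a size it lost under 10 of 18 alternatives. The filters on UMIs per gene, which are among the 18, cannot change a single gene's ratio. Ignoring leading genes in naming, also among them, changes neither of these 2 classes. The list's median was 0.71 after the profile from barcodes of 1 to 100 UMIs was subtracted and 0.45 with that of the plateau of 274 UMIs.

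Each ratio rests on counts from 144 PV-like nuclei of 1 library. Of 29 genes that the naming rule picked and that lay past 2-fold in either direction, 4 lost that size under an alternative. Among them were Jun, Dusp1 and Adrb1, and none of the 29 changed sign. Alternatives that only filter on UMIs per gene could not have changed these ratios. Nor could the one that ignored leading genes in naming, which leaves both classes as they were. Subtraction of the profile from barcodes of 1 to 100 UMIs moved 10 of the 31 genes the rule picked by over 1.5-fold, each further from equality. It took near-equal shares from PV-like (17.0%) and other GABAergic-like nuclei (16.7%), which by itself moves ratios away from equality. The direction is therefore no check. Bdnf, among the 10, had no UMI left in either class.

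**Figure D2:**
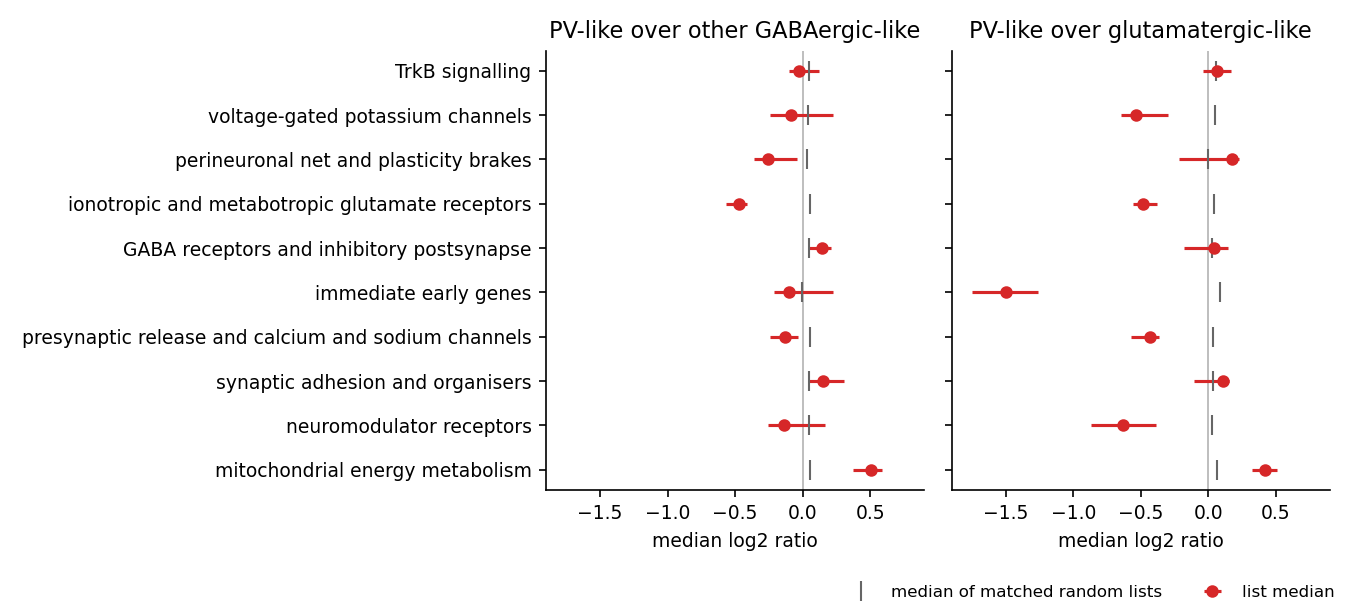
Median log2 ratio of each gene list in PV-like nuclei over other GABAergic-like nuclei (left) and over glutamatergic-like nuclei (right), library without light. Points are list medians, bars 95% intervals for counting error only, and vertical ticks the median of 10000 expression-matched random lists; energy metabolism lies at 0.50 and 0.42, glutamate receptors at -0.47 and -0.48, and immediate early genes at -1.50 on the right.

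The comparison with glutamatergic-like nuclei sets the class that PV-Cre targets against the excitatory neurons of the same library. Immediate early genes were much lower in PV-like nuclei, with a median ratio of 0.354, and energy metabolism genes were higher, with a median ratio of 1.34. Potassium channel, glutamate receptor, presynaptic and neuromodulator receptor lists had lower medians, with individual genes far apart in both directions. Of 356 measured list genes, 59 were at least 2-fold higher and 103 at most 0.5-fold, against 1555 and 2081 of all 13930 measured genes. The median log2 ratio of all measured genes was 0.04.

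Ntrk2 again differed little, at 892 CPM against 853 CPM (843 to 863), a ratio of 1.05 (0.988 to 1.11). Bdnf was far higher in glutamatergic-like nuclei, at 109.9 CPM (106.4 to 113.6, 3554 UMIs), so that PV-like nuclei stood at 0.0831-fold (0.0442 to 0.142). With the low-count and plateau profiles subtracted the ratio was 0.00365 and 0.00360, set by the pseudocount, so only a level below that of glutamatergic-like nuclei can be stated. After thinning, 28.2% of glutamatergic-like nuclei had a Bdnf UMI against 0.752% of PV-like nuclei (46.6% and 6.94% without thinning, at median depths of 10332.5 and 9741.5 UMIs). The adaptor genes Gab2 and Shc1, which couple receptor tyrosine kinases to their pathways, were 6.21-fold (5.44 to 7.07) and 2.94-fold higher (1.81 to 4.55). Of 37 TrkB signalling genes, 3 were at least 2-fold higher and 8 at most 0.5-fold, with a median log2 ratio of 0.07 (-0.04 to 0.17, percentile 52.2).

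**Figure D3:**
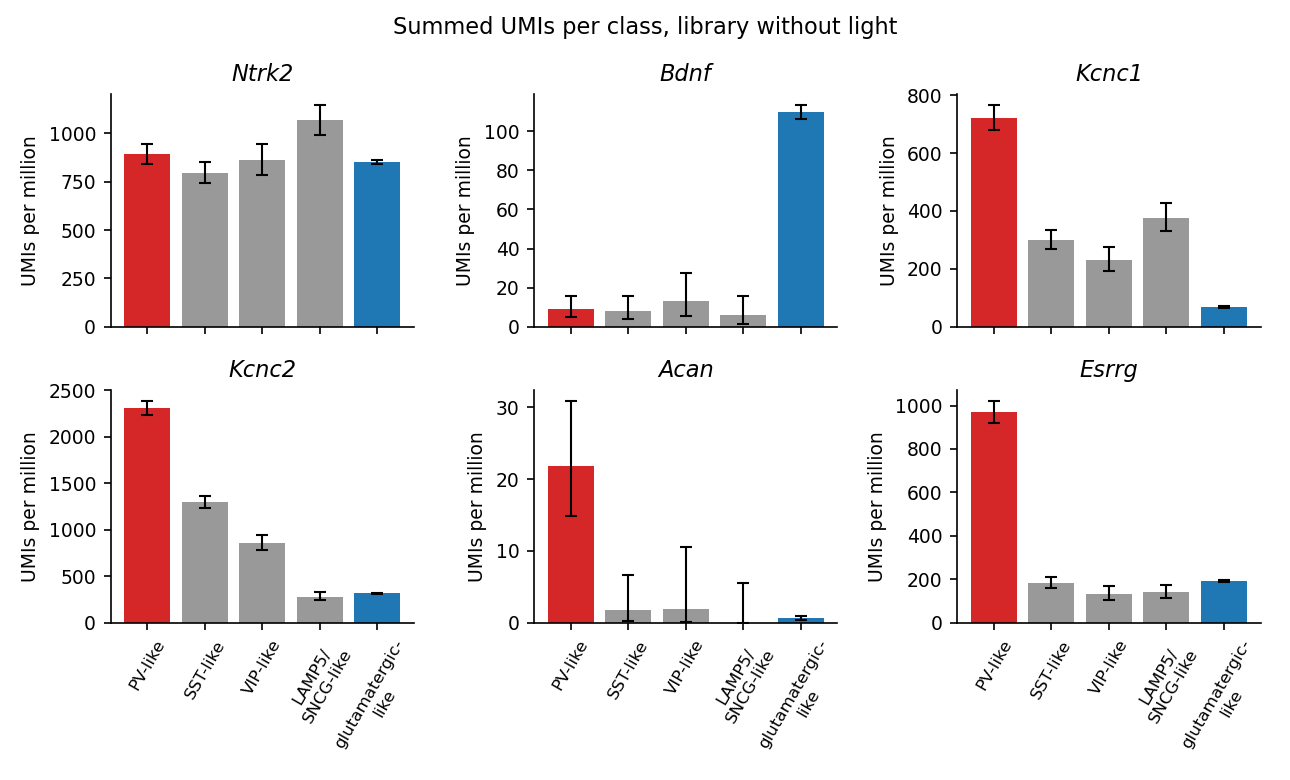
Summed UMIs as CPM of the class total in each neuronal class for Ntrk2, Bdnf, Kcnc1, Kcnc2, Acan and Esrrg, library without light; bars are class sums and error bars exact 95% Poisson intervals for counting error only. Ntrk2 lies between 797 and 1066 CPM in all 5 classes, Bdnf is highest in glutamatergic-like nuclei at 109.9 CPM, and Kcnc1, Kcnc2, Acan and Esrrg are highest in PV-like nuclei.

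Among potassium channel genes, 12 of 42 were at least 2-fold higher and 17 at most 0.5-fold, with a median log2 ratio of -0.53 (-0.65 to -0.30, percentile 0.0). Kcnc1 was 10.7-fold higher (9.91 to 11.5) and Kcnc2 7.28-fold higher (6.997 to 7.57). The auxiliary subunit genes Kcnmb2 and Kcnip1 were 267-fold (220 to 327) and 71.3-fold higher (61.7 to 82.7), and 2040-fold and 180-fold with the low-count profile subtracted. Kcnt2, a sodium-activated channel gene, stood at 0.0318-fold (0.0169 to 0.0545), with 34.2% of its level in PV-like nuclei expected from free RNA. It was at 0.00137-fold and 0.00593-fold with the low-count and plateau profiles subtracted. The first of these is set by the pseudocount, and the second rests on few of its 13 UMIs. The list of perineuronal net and plasticity brakes had 7 of 31 genes at least 2-fold higher and 8 at most 0.5-fold. Acan was 33.5-fold higher (18.7 to 61.4), Adamts15 156-fold higher (70.1 to 408) and the peptidase gene Mme 39.0-fold higher (25.9 to 59.5). Nrp1, a semaphorin receptor gene, stood at 0.0260-fold (0.00707 to 0.0665), and 57.5% of the level from its 4 UMIs in PV-like nuclei was the amount expected from free RNA. The median of the net list, 0.17 (-0.22 to 0.23, percentile 89.9), had no fixed direction, since it was -0.28 with at most 1% mitochondrial UMIs (where Acan was 56.4-fold higher) and -0.24 after the profile from barcodes of 1 to 100 UMIs was subtracted.

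Glutamate receptor genes had a median log2 ratio of -0.48 (-0.56 to -0.38, percentile 0.175), with 5 of 31 at least 2-fold higher and 8 at most 0.5-fold. Grin2d, an NMDA receptor subunit gene, was 4.84-fold higher (3.55 to 6.50) and Neto2, a kainate receptor auxiliary gene, 3.07-fold higher (2.72 to 3.45). Grm8, a presynaptic metabotropic receptor gene, stood at 0.0643-fold (0.0434 to 0.0919), and at 0.00536-fold with the low-count profile subtracted. GABA receptor genes had a median of 0.04 (-0.18 to 0.14, percentile 53.9), with 3 of 26 at least 2-fold higher and 4 at most 0.5-fold. Gabrg3 was 7.45-fold higher (7.15 to 7.76) and Kctd8 4.83-fold higher (4.24 to 5.48, and 7.66-fold with at most 1% mitochondrial UMIs), while Gabra2 stood at 0.151-fold (0.105 to 0.211) and at 0.0685-fold with the low-count profile subtracted.

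Presynaptic genes had 5 of 46 at least 2-fold higher and 17 at most 0.5-fold, with a median of -0.43 (-0.57 to -0.36, percentile 0.05), or -0.44 without the pseudocount and with the gene of 0 UMIs at its bound. Cacna2d2 was 32.7-fold higher (28.5 to 37.6) and Syt2 8.85-fold higher (7.75 to 10.1). At resolution 2.0 they were 82.0-fold and 15.1-fold higher, and with at most 1% mitochondrial UMIs 67.8-fold and 16.6-fold. Cacna2d1, a related subunit gene, stood at 0.0216-fold (0.0141 to 0.0316), and 64.0% of its level in PV-like nuclei was the amount expected from free RNA. Synaptic adhesion genes had 13 of 46 at least 2-fold higher and 10 at most 0.5-fold, with a median of 0.11 (-0.11 to 0.15, percentile 74.4). Erbb4, the neuregulin receptor of interneurons, was 775-fold higher (701 to 860), at 9307 CPM in PV-like nuclei, and Cntnap4 46.8-fold higher (42.1 to 52.0). The ratio of Erbb4 was 418 with at least 500 UMIs per nucleus, 515 in the count split and 1369 with the plateau profile subtracted. With the low-count profile subtracted no Erbb4 UMI was left in glutamatergic-like nuclei, so that ratio is set by the pseudocount. Ptprd stood at 0.0900-fold (0.0846 to 0.0955), and at 0.0419-fold with the low-count profile subtracted. Neuromodulator receptor genes had a median of -0.63 (-0.87 to -0.39, percentile 0.0100), or -0.58 without the pseudocount and with 3 genes of 0 UMIs at their bound, with 7 of 33 at least 2-fold higher and 13 at most 0.5-fold. Tacr1 was 50.5-fold higher (28.3 to 93.6) and the adrenergic receptor gene Adra1a 11.2-fold higher (9.88 to 12.6). Oprm1 stood at 0.0305-fold (0.0146 to 0.0562), at 0.0550-fold at resolution 0.5, and at 0.00173-fold and 0.0188-fold with the low-count and plateau profiles subtracted. The value of 0.00173 is set by the pseudocount. The count split took Tacr1 and Adamts15 to 88.1-fold each.

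Immediate early genes had a median log2 ratio of -1.50 (-1.75 to -1.26), below all matched lists (percentile 0.0). None of 28 was at least 2-fold higher and 17 were at most 0.5-fold. Nptx2, an activity-regulated pentraxin gene, stood at 0.0676-fold (0.0272 to 0.140), with 79.3% of its level in PV-like nuclei expected from free RNA. Among genes chosen after their values were seen, Arc stood at 0.0846-fold (0.0516 to 0.131), with 55.5% of its level in PV-like nuclei expected from free RNA. At the marker-scaled share, 2.52 times higher, the expected amount exceeds the Arc level seen. Npas4 stood at 0.229-fold (0.162 to 0.315), whereas Fos had a ratio of 0.953 (0.779 to 1.16). Energy metabolism genes had a median of 0.42 (0.32 to 0.51, percentile 99.8), with 4 of 36 at least 2-fold higher and 1 at most 0.5-fold. Esrrb was 13.0-fold higher (7.10 to 23.1) and Esrrg 5.08-fold higher (4.79 to 5.39), and Esrrg 9.41-fold at resolution 2.0. UMIs of mitochondrially encoded genes were 1.46-fold higher (1.38 to 1.53) in the same comparison. Ldha, a lactate dehydrogenase gene, stood at 0.256-fold (0.151 to 0.406), with 61.3% of its level in PV-like nuclei expected from free RNA.

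No replicate test was possible here either. All 31 named genes past 2-fold in either direction stayed past it in the same direction under each of 16 alternatives. Ratios moved by over 1.5-fold under several. The filters on UMIs per gene are among the 16 and cannot change a single gene's ratio. Subtraction of the low-count profile moved 14 of the 32 named genes by over 1.5-fold, each further from equality. It took the immediate early gene median to -3.66. With the plateau profile, whose composition differs, 9 genes moved and the median was -2.12. Cacna2d1, Nptx2, Nrp1 and Ldha, like Bdnf, came to at most 0.0128-fold with either profile subtracted. These values are set by the pseudocount and are not measured bounds. Only a level below that of glutamatergic-like nuclei can be stated.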

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

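The tests of the transgene, the free RNA tests and the test of mitochondrially encoded UMIs were chosen after the results were seen; the tests of gene length and of ribosomal protein genes were written before their values were seen. No biological explanation was tested, because only the library without light was analysed here.

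Outside the comparisons, 2 unnamed clusters carried a marker of another cell type above the limit that a count of 0 allows. Cluster 13, 73 nuclei (1.97% of those retained) with a median of 1430 UMIs, had Inpp5d, a microglial marker, at 112.2 CPM (67.5 to 175.2, 19 UMIs in 5 nuclei), against 3.09 CPM in glutamatergic-like nuclei and 3.66 CPM in empty droplets. The microglial genes P2ry12 and Cx3cr1 stood there at 47.2 CPM (20.4 to 93.1) and 41.3 CPM (16.6 to 85.2), against 4.81 and 9.16 CPM in empty droplets and 31.6 and 15.3 CPM in glutamatergic-like nuclei, so P2ry12 does not set the cluster apart from neurons. Slc17a7 stood at 377.9 CPM in the cluster, whose marker scores were 0.656 for glutamatergic neurons and 0.649 for microglia. Cluster 10, 182 nuclei (4.91%) with a median of 14876 UMIs, had Aldh1l1, an astrocyte marker, at 62.1 CPM (53.6 to 71.6, 190 UMIs in 94 nuclei), against 6.19 CPM in glutamatergic-like nuclei. This marker is no independent sign, because cluster 10 stayed unnamed only for having it among its 10 leading genes. The astrocyte genes Slc1a3 and Aqp4 had 0 UMIs there, and the glutamatergic gene Slc17a7 stood at 255.3 CPM, with a UMI in 96.2% of nuclei. Rorb had one in 98.9%. Scores were 0.670 for glutamatergic neurons and 0.117 for astrocytes. By these values the 182 nuclei are glutamatergic-like, yet they are missing from that class and from the 3405 neuronal nuclei.

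The absence of the transgene feature from PV-like nuclei is the first pattern to weigh, and none of the tests excludes an explanation. Of 16654 genes detected in these nuclei, 3316 (19.9%) lay below the limit of 2.11 CPM, so a transcript of low abundance could be missed at this depth. Whether the captured 3' end lies outside the feature's sequence cannot be told apart from a lack of transcript, because the library held 1 UMI of it and no nuclei known to carry the construct. Few carrying nuclei may equally account for it: the limit of 2.08% covers nuclei with a UMI and leaves the share that carries the construct open.

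The low level of immediate early genes in PV-like against glutamatergic-like nuclei is the second. Free RNA of the empty-droplet profile is argued against as the whole source. To make the difference it would have to supply a median of 22.4 percentage points (quartiles 10.5 and 35.6) more of the UMIs of glutamatergic-like nuclei than of PV-like nuclei, whereas GABAergic markers limit it there to 3.42% (upper end 3.72%). Gene length was argued against by lists matched on expression and length, among which the median lay at percentile 0.0. Cytoplasmic RNA carried with nuclei would lower ribosomal protein genes too, but 77 of these had a median log2 ratio of 0.00689 (quartiles -0.28 and 0.21). What sets the level is left open.

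The high level of energy metabolism genes in PV-like against other GABAergic-like nuclei is the third. Free RNA would have to supply a median of 6.51 percentage points (quartiles 2.78 and 14.5) more of the UMIs of PV-like nuclei, whereas glutamatergic markers put the excess at 0.138 points (upper end 1.57). The median lay at percentile 100 of lists matched on expression and length, and 53 ribosomal protein genes had a median log2 ratio of -0.0442. These argue against free RNA, gene length and carried cytoplasm as the whole cause. UMIs of mitochondrially encoded genes were 1.65-fold higher in PV-like nuclei (1.55 to 1.76) and 1.46-fold higher than in glutamatergic-like nuclei. Mitochondria attached to nuclei stay a possible explanation, although listed genes are nuclear encoded. The test cannot decide, because a difference between the cells themselves in these transcripts would give the same values. The pattern is therefore not called biological.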

How the results depend on the processing

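The 5 alternatives on the top 6% of doublet scores, leading genes in naming, empty-droplet free RNA, named classes only and equal class weights were chosen after seeing the data. Over 18 alternatives and 27 main results, 405 of 433 values stayed within counting error or within 1.5 times a count, 28 moved beyond it and 0 reversed a called direction. Ignoring leading genes in naming leaves the PV-like and other GABAergic-like classes unchanged, so it could not move a value between them. The PV-like share ranged from 30.3 to 32.2% and PV-like nuclei from 135 to 147. Nuclei retained ranged from 3466 to 4374. The GABAergic-like share moved to 15.6% with at most 1% mitochondrial UMIs and to 15.4% at resolution 2.0, and its lowest value was 12.7%.

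Against other GABAergic-like nuclei, subtracting the profile of barcodes of 1 to 100 UMIs, which differs in make-up from empty droplets of the plateau, took immediate early genes to 0.71, energy metabolism to 0.83 and list genes at least 2-fold higher from 35 to 55. With the empty-droplet profile the 2 medians were 0.45 and 0.69. Removing the top 6% of doublet scores gave -0.37 for the net list (perineuronal net and plasticity brakes) and 0.37 for energy metabolism. Named classes only gave potassium channels 0.26, as did the count split, and equal weights gave glutamate receptors -0.61. With at least 10 UMIs per gene, the net list was at -0.37 and neuromodulator receptors at -0.36. With at least 1 UMI, neuromodulator receptors were at -0.60 and list genes at most 0.5-fold rose from 52 to 82, as more genes are measured.

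Against glutamatergic-like nuclei, subtracting the profile of barcodes of 1 to 100 UMIs gave immediate early genes -3.66, presynaptic genes -0.59, the net list -0.24 and energy metabolism 0.31. With the empty-droplet profile immediate early genes were at -2.12 and presynaptic genes at -0.61. The net list was at -0.28 with at most 1% mitochondrial UMIs, 0.28 with at least 10 UMIs and 0.42 with at least 1 UMI. The last setting also gave neuromodulator receptors -0.38 and moved the median of all genes from 0.04 to 0.35. Energy metabolism was at 0.32 without the top 6% of doublet scores and 0.25 from the mean per nucleus. Apart from the gene filters, the cause was not tested. Counts per list stayed within 1.5 times in 653 cases and moved in 45. Ratios of named genes stayed within counting error in 959 cases and moved in 111. The 959 include the filters on UMIs per gene, which cannot change a single gene's ratio. They also include the naming alternative against other GABAergic-like nuclei, which could not change one either.

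No paired analysis was possible because only 1 library was analysed here. The library's depth limits low genes most: with 1422676 UMIs in PV-like nuclei, 3 UMIs are 2.11 CPM.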

Other observations

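The comparisons and genes in this part were chosen after their values were seen. PV-like nuclei fell into sub-clusters of 88 and 56 nuclei, made without the list genes. Of 227 list genes with at least 50 UMIs, 7 were at least 2-fold higher in the smaller sub-cluster and 8 at most 0.5-fold. The muscarinic receptor gene Chrm2 stood at 207.2 CPM there against 4.66 CPM in the larger, a ratio of 44.5 (16.9 to 165.9), the serotonin receptor gene Htr2c was 9.63-fold higher (5.55 to 17.9) and the kainate receptor gene Grik1 3.86-fold higher (3.26 to 4.59). In the larger sub-cluster the adhesion gene Il1rapl2 stood at 1789 CPM against 133 CPM, and the smaller stood at 0.0743-fold (0.0581 to 0.0937). Grin2a, an NMDA receptor subunit gene, stood at 0.318-fold (0.281 to 0.359) and Fosb at 0.212-fold (0.102 to 0.400) in the smaller. Pvalb was at 124 CPM in the smaller and 183 CPM in the larger, and Tac1 at 77.9 and 18.6 CPM.

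Glutamatergic-like nuclei were also far from uniform. Of 261 list genes with at least 1000 UMIs, 44 differed at least 10-fold between their highest and lowest of 10 clusters. Bdnf ranged from 18.4 CPM (14.4 to 23.2) in cluster 6, led by Foxp2 and Syt6, to 215.3 CPM (199.6 to 231.8) in cluster 3, led by Calb1 and Cck. Cluster 1, led by Tshz2, held Nxph1 at 2111 CPM and Gabrg3 at 2173 CPM, against 2.94 CPM for Nxph1 in cluster 7 and 20.2 CPM for Gabrg3 in cluster 5. Bdnf stood at 257.3 CPM in empty droplets of the plateau, so free RNA can make up part of the 18.4 CPM in cluster 6. The ratio of 0.0831 for Bdnf between PV-like and glutamatergic-like nuclei is thus an average over clusters that differ 11.7-fold before any subtraction of free RNA. With the profiles of barcodes of 1 to 100 UMIs and of the plateau subtracted it was 0.00365 and 0.00360. Both values are set by the pseudocount, so only a level below that of glutamatergic-like nuclei can be stated.

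Xist had 21 UMIs in 3709 nuclei, never more than 1 in a nucleus, but stood at 74.8 CPM in barcodes of 1 to 100 UMIs, against 0.619 CPM in glutamatergic-like nuclei and 0.229 CPM in the plateau of 274 UMIs. The source of these UMIs was not tested. The Y-linked genes Eif2s3y and Uty had a UMI in 59.8% and 56.3% of nuclei.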
